A study of Nicotiana attenuata with 2 samples.

How the data were processed

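The series holds RNA sequencing of leaves of wild-type *Nicotiana attenuata*, a wild tobacco, taken 1 day after mock treatment or 1 day after inoculation with the necrotrophic fungus *Alternaria alternata*. Per the labels, the leaves were at the source-sink transition on rosette-stage plants 35 days old, total RNA was extracted with Trizol, and sequencing was done on an Illumina HiSeq2000. Each group has 1 library, so no difference below has a replicate check and no p-value across genes is given.

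The authors deposited a single table of 58148 assembled sequences with their lengths, raw fragment counts and FPKM in each library, and best database hits. Per the file headers, the counts are raw fragments with the library total in the header, 18.4 M (M, 1e+06) in mock and 18.0 M in infected, and both columns sum to those totals. The authors' FPKM values equalled fragments per kilobase and per 1e+06 fragments of these totals to within 5.0e-05. The assembler, the aligner, the counting program and the annotation search settings are not given in the sources used here. The sequences are contigs of an assembly and not genes of a genome: 23398 belong to 6986 clusters of related contigs, so reads of 1 gene, or of close paralogs, can be split among several of them, and 34750 stand alone. No genome coordinates were used. None of the Nr accessions matched the gene table of the reference assembly NIATTr2 (0 matches), so that table was not used. Names are those of the deposited Swiss-Prot hit, or of the Nr hit where there was none: 32141 sequences had an informative name. The best Nr hit was a *Solanum* sequence for 31449 sequences and a *Nicotiana* sequence for 2711, so a name marks similarity to a protein of another plant. No deposited Nr or Swiss-Prot name matched the fungal patterns (0 sequences). The nucleotide (Nt) hits, which 44686 sequences have, were not searched for fungal names. The Nr hits name plants, algae, oomycetes and other protists and no fungus, animal or bacterium, so this 0 reflects the annotation and not the sample. The organisms of the Swiss-Prot hits were not part of the names searched. A sequence of the inoculated fungus would carry an Nr hit to one of those Nr organisms or none. It could not be set apart by the names searched. The table has no fold changes or p-values of the authors' own to compare with.

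From the deposited counts, a log2 ratio of infected over mock was computed per sequence on counts per 1e+06 fragments of the library total (CPM), with a pseudocount of 0.5 fragments. Each ratio has an exact conditional binomial (Clopper-Pearson) 95% interval, which covers counting error only. A sequence entered the comparison when its mean over both libraries was at least 1 CPM, which 26883 sequences met, 18176 of them named, and it was called higher or lower when the libraries were at least 2-fold apart. A fold against a library with 0 fragments is given as a lower bound, computed against a floor of 3 fragments in that library (0.163 CPM in mock and 0.166 CPM in infected); this bound can lie above the lower end of the two-sided counting interval.

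A set of 45 gene lists was fixed as text patterns on the names before the data were examined. They cover hormone pathways (jasmonate biosynthesis and response, ethylene biosynthesis and signalling, salicylate, abscisic acid, auxin, and gibberellin with cytokinin and brassinosteroid), defence proteins, specialised metabolism, photosynthesis, transcription factor families, signalling, detoxification, cell walls, carbohydrates, chaperones, ribosomes, cell cycle, protein turnover, housekeeping genes, trichome markers, fungal names, organelle genes and transposons. For each list the median log2 ratio is given with an order-statistic 95% interval over its members, and with its percentile among 10000 random lists of the same size matched on mean level in 20 bins. The percentile describes these 2 libraries only. Setting sequences with 0 mock fragments at their bound moved no list median (largest difference 0 over 44 lists). The named sequences follow a rule also fixed beforehand: the 10 highest and 10 lowest log2 ratios among named sequences with a mean of at least 10 CPM, the 2 most abundant and the 2 furthest apart in each list with a mean of at least 5 CPM, each with 1 per identical name, and every sequence annotated as feruloyl-CoA hydroxylase. The text names only part of these, more often the sequences furthest apart than the most abundant ones, so a named fold does not stand for its list, nor for other contigs of the same name.

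The alternatives were TMM scaling (edgeR 4.0.16), median-of-ratios scaling (DESeq2 1.42.0), no level filter, a mean of at least 5 CPM, pseudocounts of 0.05 and 2.5 fragments, leaving out fungal-named sequences, keeping 1 sequence per name, the authors' FPKM with a pseudocount of 1, a 4-fold rule, a counting interval wholly beyond 2-fold, and random lists matched on length. The scaling factors were first computed over all sequences, where the median of ratios gave a log2 factor of 0, and were then restricted to sequences with a mean of at least 1 CPM; that restriction was made after the first factors had been seen, and both sets are kept. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and R 4.3.3 were used. On simulated counts for the infected against mock comparison, 200 sequences were altered, and 181 of them were among the 26849 that met the level filter. The 2-fold rule with that filter called 4% of those altered 1.5-fold, 88% at 2.5-fold, 90% at 4-fold and 82% at 8-fold, without it 6%, 90%, 100% and 100%, and it called 0.506% of the 26668 unaltered ones that met the filter; the simulation holds counting error and no variation between plants.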

Results

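The comparison asks which transcripts differ in *N. attenuata* leaves 1 day after inoculation with *A. alternata*. The mock library held 18.4 M fragments (M, 1e+06) over 53634 sequences and the infected library 18.0 M over 54716. The 10 most abundant sequences took 12.2% of the mock library and 7.65% of the infected library.

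In the infected library 44 of 74 sesquiterpene and mevalonate sequences, 31 of 45 glutathione S-transferases and 21 of 43 ethylene synthesis sequences were at least 2-fold higher, and 41 of 135 light-reaction sequences were at least 2-fold lower. HMG-CoA reductase (Unigene21445), the enzyme that commits carbon to the mevalonate pathway, had a log2 ratio of 4.52 (interval 4.46 to 4.59), with 1880 mock and 42236 infected fragments. Acidic endochitinase Q (Unigene18778), which cleaves chitin, was 88.6-fold higher, and glutathione S-transferase parA (Unigene23498) was 304-fold higher. Geranyllinalool synthase (Unigene18995), which supplies the backbone of the leaf's defensive diterpene glycosides, was 5.92-fold lower. Of 26883 sequences, 3507 were at least 2-fold higher in the infected library and 1634 at least 2-fold lower. Higher sequences made up 68.2% of these, and 51.7% under TMM scaling, which gave 2576 higher and 2409 lower. The median log2 ratio of all sequences was 0.19, and TMM scaling shifted it by -0.19; list medians below are best read relative to that value. These are single libraries, and the intervals carry counting error but no variation between plants.

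**Figure D1:**
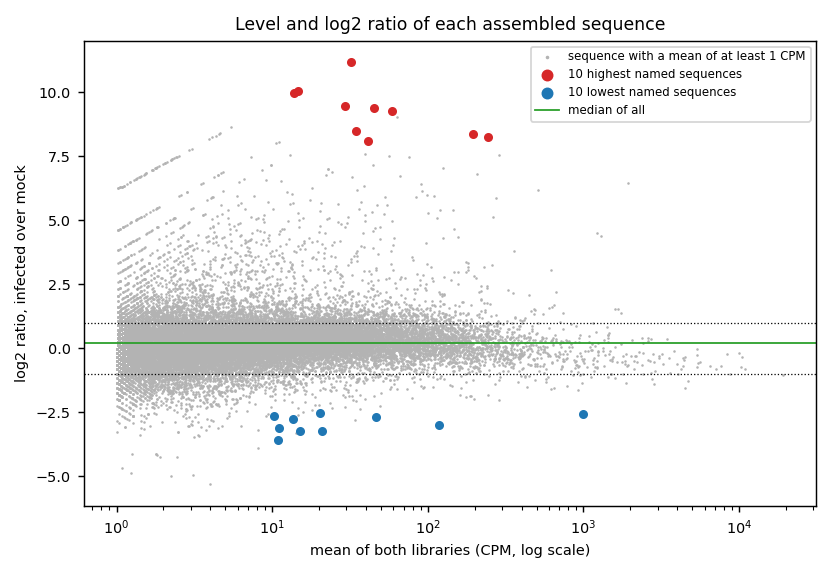
Each grey point is 1 of 26883 assembled sequences, with the mean of both libraries in CPM on a log axis and the log2 ratio of infected over mock. Red and blue points are the 10 highest and 10 lowest named sequences, dotted lines mark 2-fold, and the green line is the median of all (0.19); higher sequences (3507) outnumber lower ones (1634).

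Among the 10 named sequences with the highest ratios, 3 had no fragment in mock, and their folds are bounds against the floor. UDP-glycosyltransferase 85A2 (Unigene23624) had 1157 infected fragments and was at least 394-fold higher, a chloroplast polyphenol oxidase (Unigene27642) had 528 and was at least 180-fold higher, and expansin-like B1 (Unigene24552) had 501 and was at least 171-fold higher; the counting intervals of the 3 begin at 320, 146 and 138. Snakin-1 (Unigene18934), named after an antimicrobial peptide, had 2 mock and 1635 infected fragments, a ratio of 668 with an interval from 231 to 6909. A cytochrome P450 71A1 sequence (CL2669.Contig9) had 3 and 1243 fragments, a ratio of 363 with an interval from 145 to 2058, while other contigs of its cluster and name were lower (log2 ratio -1.59 for CL2669.Contig1, -2.01 for CL2669.Contig7, and 867 mock and 424 infected fragments for CL2669.Contig8). A 21 kDa seed protein-like sequence (Unigene10470) was 333-fold higher and a miraculin-like sequence (CL2057.Contig3) 278-fold higher. The miraculin-like sequence had 5 mock fragments and an interval from 131 to 943. At the other end stood bHLH63 (Unigene17409), with 374 mock and 30 infected fragments and a log2 ratio of -3.59, tetraspanin-8 (Unigene16189), 9.36-fold lower, the ethylene-responsive factor ERF017 (Unigene13418), 8.68-fold lower, and an apyrase (CL1329.Contig3), 8.06-fold lower.

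The sesquiterpene and mevalonate list, which holds the route to the phytoalexin capsidiol, had 44 of 74 sequences higher and 5 lower. Its median log2 ratio was 1.91 (interval 0.98 to 2.85), at percentile 100 of matched random lists. 5-epi-aristolochene synthase 3 (Unigene22792), which forms the sesquiterpene skeleton, was 39.7-fold higher, with 39 mock and 1534 infected fragments. Premnaspirodiene oxygenase (Unigene14492), a cytochrome P450, had 3 and 2116 fragments, a ratio of 617 with an interval from 246 to 3501. A further HMG-CoA reductase (Unigene384) was 7.88-fold higher. In the diterpenoid and plastid isoprenoid list none of 12 sequences was higher and 3 were lower (median -0.30, percentile 1.53, and 5.44 with 1 sequence per name). Deoxyxylulose-5-phosphate synthase (Unigene9691), at the entry of the plastid route, was 3.09-fold lower.

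Of 10 sequences annotated as feruloyl-CoA hydroxylase, the enzyme that leads to the coumarin scopoletin, CL2514.Contig3 was 42.0-fold higher, with 5074 infected fragments and an interval from 35.3 to 50.9. CL4998.Contig3 was 4.05-fold higher, Unigene9532 2.98-fold and Unigene13021 2.14-fold, which is 0.90 on the log2 scale under TMM scaling. These names are Swiss-Prot hits. The Nr hit of CL2514.Contig3 is only an oxidoreductase and that of CL4998.Contig3 a gibberellin 20 oxidase 1-like protein. Those of Unigene9532 and Unigene13021 also name feruloyl-CoA hydroxylase. CL2514.Contig2, below the level filter at a mean of 0.305 CPM, had 0 and 11 fragments, at least 3.75-fold higher against the floor (lower end of the counting interval 2.57). The log2 ratio of Unigene25822 was 0.26 (interval -0.11 to 0.64), and the other 4 had at most 4 fragments in either library. The wider phenylpropanoid and coumarin list had 25 of 69 sequences higher and 7 lower (23 and 10 under TMM scaling; median 0.25, percentile 65.2, and 0.49 at 97.7 with 1 sequence per name). A caffeic acid O-methyltransferase (CL5590.Contig1) was 21.6-fold higher, while the most abundant member, 4-coumarate CoA ligase 1 (CL4141.Contig2), had a log2 ratio of -0.45. In the lignin branch 11 of 37 were higher and 4 lower (7 and 5 under TMM scaling; median 0.37, percentile 88.4), with a median of 0.70 at percentile 98.4 with 1 sequence per name and 0.42 at 99.1 on the authors' FPKM. Its laccase-14 (Unigene14572) was 178-fold higher.

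**Figure D2:**
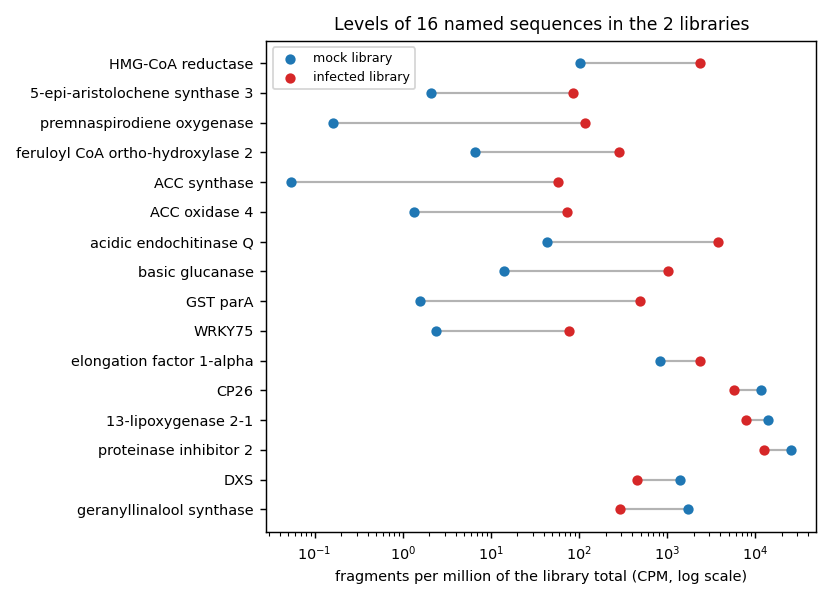
Level of 16 named sequences in the mock library (blue) and the infected library (red), in CPM on a log axis, 1 library per group. The points of acidic endochitinase Q lie 88.6-fold apart and those of geranyllinalool synthase 5.92-fold apart in the opposite direction.

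Of 43 ethylene synthesis sequences, 21 were higher and 1 lower (median 0.96, percentile 100, and 97.4 with no level filter; 19 higher and 3 lower under TMM scaling). An ACC synthase (Unigene13649), which makes the ethylene precursor, had 1 mock and 1051 infected fragments, a ratio of 714 with an interval from 192 to 42495. An ACC oxidase 4 contig of 220 bases (CL1053.Contig7) was 52.6-fold higher. In its cluster the log2 ratios were 1.07 for CL1053.Contig1, 2.33 for CL1053.Contig5, 2.91 for CL1053.Contig6, 3.78 for CL1053.Contig2, 4.67 for CL1053.Contig3 and 4.76 for CL1053.Contig4. Contigs of 1 cluster count separately in the list. The 2 most abundant members were an ACC oxidase (Unigene9776), 2.09-fold higher, and an ACC oxidase homolog (CL6247.Contig2), with a log2 ratio of -0.50. In ethylene signalling 16 of 124 were higher and 10 lower (median -0.01, percentile 0.12, and 21.9 with 1 sequence per name; 14 and 18 under TMM scaling), with ethylene-responsive factor 14 (Unigene747) 12.3-fold higher; 1 member is a proteinase inhibitor. Jasmonate biosynthesis had 7 of 26 higher and 1 lower (6 and 2 under TMM scaling; median 0.18, percentile 43.4). Its dominant sequence, a chloroplast 13-lipoxygenase (CL2389.Contig1), had 258507 mock and 143382 infected fragments, a log2 ratio of -0.82. A sequence named 12-oxophytodienoate reductase 1 (CL3749.Contig1) was 26.1-fold higher, with 62 and 1595 fragments, and the more abundant CL3749.Contig2 of the same name had 3804 and 3712. The list was set by name and also counts a probable 9-lipoxygenase (CL1293.Contig4), which was 5.83-fold higher. In the jasmonate response list 9 of 56 were higher and 11 lower (median -0.29, percentile 0, and 15 lower under TMM scaling). Proteinase inhibitor 2 (CL2050.Contig5), the most abundant sequence in both libraries, was 2.05-fold lower. Proteinase inhibitors did not all fall: a type-2 inhibitor named CEVI57 (Unigene27303) was 51.8-fold higher, with 9 mock and 481 infected fragments. The polyphenol oxidase named above (Unigene27642) also belongs to this list. The salicylate list had 10 of 34 higher and 2 lower (9 and 3 under TMM scaling), with a median of 0.22 at percentile 60.6. Basic PR-1 (CL3218.Contig2) was 34.4-fold higher, with 8 mock fragments and an interval from 18.3 to 85.5.

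Pathogenesis-related proteins had 41 of 105 sequences higher and 4 lower (median 0.35, percentile 98.1). Their summed share of fragments was 0.262% in mock and 0.873% in infected, and acidic endochitinase Q alone had 68977 infected fragments. A basic vacuolar glucanase (Unigene7592) was 72.4-fold higher and the protein STH-2 (Unigene2092) 77.5-fold higher. STH-2 had 8 mock fragments and an interval from 41.5 to 192. The percentile of this list was 83.4 with a mean of at least 5 CPM, 97.0 with 1 sequence per name and 96.0 with random lists matched on length. Among WRKY factors, regulators of defence genes, 21 of 70 were higher and 2 lower (median 0.43, percentile 99.6; 78.8 with a mean of at least 5 CPM and 97.1 with 1 sequence per name; 16 and 4 under TMM scaling). WRKY45 (Unigene27432) was 64.8-fold higher, with 7 mock fragments and an interval from 33.4 to 174. WRKY75 (Unigene20817) was 31.8-fold higher. Receptor-like kinases had 106 of 499 higher and 22 lower (88 and 31 under TMM scaling), but a median of 0.18 at percentile 23.3, which is -0.015 under TMM scaling; with no level filter the percentile was 100. The chitin elicitor receptor kinase 1 sequence (CL4675.Contig1) was 27.0-fold higher.

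Of 45 glutathione S-transferases 31 were higher and none lower, with a median of 3.02 (interval 1.64 to 4.14, percentile 100). Class III peroxidases had 17 of 34 higher and 1 lower (median 1.02, percentile 100), UDP-glycosyltransferases 43 of 108 and 8 (median 0.75, percentile 100), cytochrome P450s 52 of 160 and 12 (median 0.41, percentile 99.99), and ABC transporters 31 of 119 and 0 (median 0.45, percentile 99.98). The P450 list shares 23 sequences with the sesquiterpene list, and its percentile was 54.9 with 1 sequence per name and 96.8 on the authors' FPKM. Under TMM scaling 20 P450s, 13 glycosyltransferases, 2 peroxidases and 1 ABC transporter were lower, and 23 ABC transporters higher. Pleiotropic drug resistance protein 1 (Unigene11784), an ABC transporter, was 14.4-fold higher, and UDP-glycosyltransferase 74E2 (Unigene10327) was 2.97-fold lower.

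Light-reaction sequences had 41 of 135 members at least 2-fold lower and none higher (66 lower under TMM scaling). The median log2 ratio was -0.80 (interval -0.88 to -0.72, percentile 0), and the summed share of fragments was 13.5% in mock and 8.20% in infected. CP26 (Unigene24264), a light-harvesting protein, was 2.02-fold lower, with 216317 mock and 104620 infected fragments, and chlorophyll a-b binding protein 48 (Unigene4606) was 5.88-fold lower. Calvin cycle sequences had a median of -0.52 at percentile 0 with 1 of 53 lower and none higher (9 lower under TMM scaling), and chlorophyll biosynthesis a median of -0.34 at percentile 0.03 with 5 of 27 lower and 2 higher. The magnesium chelatase subunit ChlH (Unigene24362) had a log2 ratio of -0.96.

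Cytosolic ribosomal protein sequences were higher together: 164 of 324 were at least 2-fold higher and none lower (97 higher under TMM scaling), with a median of 1.00 (interval 0.95 to 1.05, percentile 100). Elongation factor 1-alpha (CL2488.Contig3), which brings aminoacyl-tRNA to the ribosome, was 2.87-fold higher, while the housekeeping list that holds it had a median of 0.27 at percentile 79.98, with 13 of 188 higher and 1 lower (8 and 3 under TMM scaling). Chloroplast ribosomal proteins had a median of -0.15 at percentile 0, with 10 of 109 higher and 2 lower (5 and 4 under TMM scaling).

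**Figure D3:**
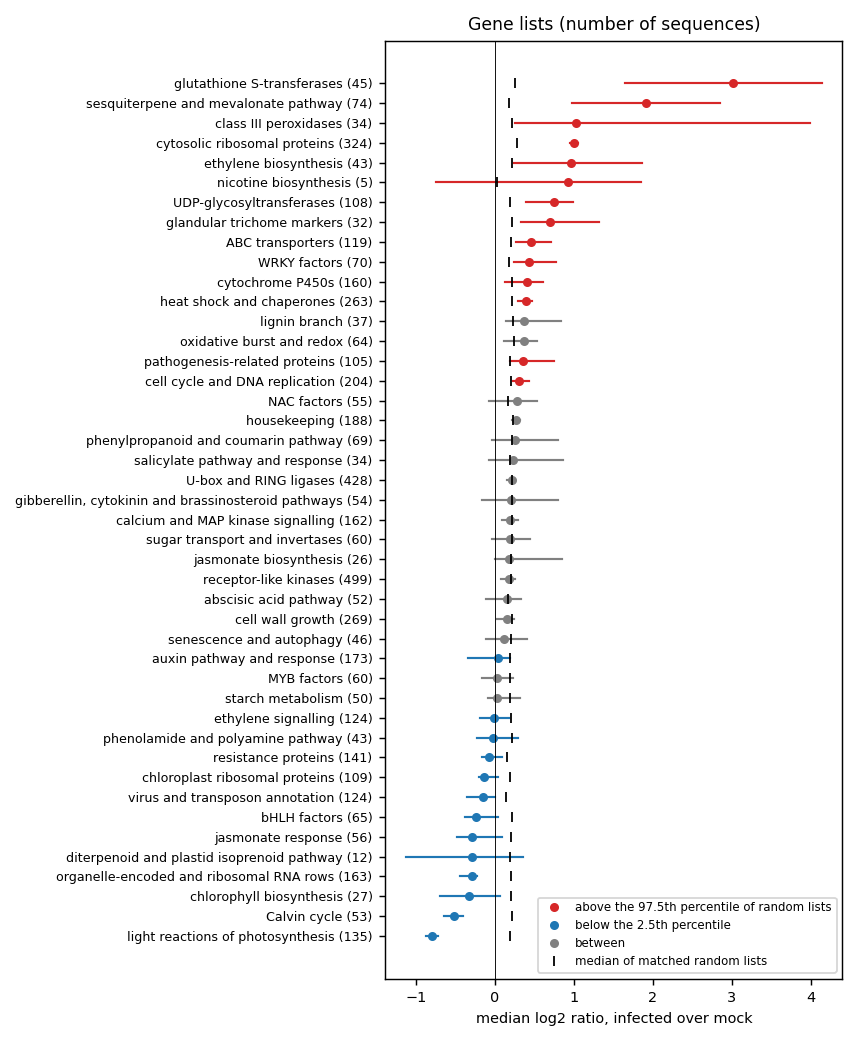
Median log2 ratio of infected over mock for 44 gene lists, with the number of sequences in brackets; bars are 95% order-statistic intervals over members and black ticks the median of random lists matched on level. Red lists lie among the highest 2.5% of random lists (14 lists) and blue lists among the lowest 2.5% (13 lists).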

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

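Of the tests in this part, only the clock-gene test was written before its values were seen, and its pattern for TOC1 was corrected and its resampled interval added after a first run; the other 6 were written after related values had been seen, and the test of chance detection replaced an earlier one that only restated the pattern.

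The 495 sequences whose best Nr hit is not a seed plant (an alga, moss, oomycete or protist) stood out because they carried more fragments in the infected library, 6668, than in mock, 4482, and 80 of them, with names such as necrosis-inducing protein NPP10 (29 fragments), a GH18 endochitinase (32) and a pectate lyase (30), had at least 5 infected fragments and none in mock, and 3 the reverse; for seed-plant hits the numbers were 425 and 139. Chance detection at low levels would leave seed-plant sequences with as many pooled fragments in the infected library alone as often. Random draws of these, matched to the 174 of the 495 with at least 5 pooled fragments, held 6.03 such sequences (interval 2 to 11), against the 80 observed. RNA of another organism may be present. Of the ribosomal protein fragments with such a hit 66.2% were in the infected library, between the bounds of 60% and 75% set for the test. For seed-plant hits it was 64.9%, already above the bound of 60%, so a share above that bound does not set these hits apart. The 66.2% cannot decide, because it pools 21 ribosomal sequences found in the infected library alone with 38 found in both libraries. This explanation therefore stays open. Split by kind after that outcome, the share was 91.5% for mosses and their allies (interval 82.5% to 96.8%), 71.2% for green, red and glaucophyte algae, 59.4% for other algae and protists and 44.7% for oomycetes (interval 33.3% to 56.6%), and it was 76.6% for barley hits, which count among seed plants here and had 27 infected-only and 0 mock-only sequences. Core housekeeping names, also added then, made up 35% of the infected-only sequences with a hit outside seed plants, 43.7% of those in both libraries, and 11.8% and 3.32% for seed-plant hits.

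Light-harvesting and photosystem sequences were lower in the infected library. A few abundant sequences taking a larger share of that library would lower sequences of the same level alike, but the list median lay -0.99 log2 units from that of level-matched random lists. The 10 and 100 most abundant sequences of each library also took a smaller share of the infected library (7.65% and 27.3%) than of mock (12.2% and 37.4%). The 100 include light-reaction sequences such as CP26, so this smaller share partly restates the pattern and is not independent of it. A difference in time of day stays open: the medians of morning and evening clock genes with a mean of at least 5 CPM, a limit not in the written test, lay 0.51 log2 units apart, under the bound of 1, but the 7 morning and 5 evening sequences, the latter all ELF3, ELF4 or ELF4-like names, gave a resampled interval of morning minus evening from -1.30 to 0.86. Over all 11 morning and 17 evening sequences, a value added afterwards, the difference was -0.64 (interval -0.98 to -0.32), inside the bound but from contigs that can share a gene, so harvest time is not excluded. Infection itself, the factor in the design, was not tested beyond the single pair of libraries.

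Cytosolic ribosomal protein sequences were higher in the infected library. Separately assembled fungal sequences would be absent from mock. The level filter left 0 such sequences among the 324 tested, so a rise confined to them could not have appeared. The values show only that sequences present in mock were higher. The 249 sequences with at least 100 mock fragments had a median log2 ratio of 1.00, and the 35 with at least 1000 had 0.76 (interval 0.66 to 0.89), 5 of them at least 2-fold higher. A length or level bias would move other short sequences alike, but the median lay 0.65 above that of random lists matched on both. A younger leaf in the infected library as the only difference would be expected to raise chloroplast ribosomal proteins too, and their list lay -0.34 log2 units from random lists. Fungal reads aligned to conserved plant sequences, and infection itself, may still account for the pattern and were not tested.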

How the results depend on the processing

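The 2 libraries leave each ratio without a replicate check, and low counts limit its precision. The restriction of the scaling factors, the factors over all sequences and the run without non-seed-plant hits were chosen after seeing the data. The counts of 3507 higher and 1634 lower sequences moved by over 1.5 times under rules that take in more or fewer sequences by construction: 9989 and 8215 with no level filter, 1819 and 460 with a mean of at least 5 CPM, 1049 and 235 at 4-fold, 1854 and 528 with the counting interval wholly beyond 2-fold, and 2035 higher with 1 sequence per name. TMM scaling gave 2576 and 2409 and the median of ratios 2580 and 2405; over all sequences these became 2843 and 2103, and 3330 and 1760. Without non-seed-plant hits 26853 of 26883 sequences were left, 3498 higher and 1629 lower. Leaving out fungal names removed no sequence, so that run tests nothing. The numbers of lists above (14) and below (13) the random lists stayed within 1.5 times in every alternative run for lists, from 10 to 14 and from 9 to 13, though which lists they were differed. The medians of receptor-like kinases (-0.015 with TMM, -0.013 with the median of ratios), cell wall growth (-0.043 and -0.042) and calcium and MAP kinase signalling (-0.00093 with TMM) turned negative; these are the lists whose interval excluded 0. With TMM the medians of 7 lists whose interval held 0 turned negative too: jasmonate biosynthesis, abscisic acid, auxin, sugar transport, starch, senescence and MYB factors. Of 106 named sequences at least 2-fold apart, 100 stayed so under TMM scaling and none took the opposite sign. No paired analysis was possible because each group has 1 library.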

Other observations

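The heat shock and chaperone list had 62 of 263 sequences higher and 13 lower in the infected library (49 and 20 under TMM scaling). Its median was 0.39 at percentile 99.99, which was 79.8 with a mean of at least 5 CPM and 91.6 with 1 sequence per name. A 17.1 kDa class II heat shock protein (Unigene8567) was 69.2-fold higher, with 6 mock fragments and an interval from 34.2 to 205. Cell-wall invertase (CL1400.Contig2), which splits sucrose outside the cell, was 37.9-fold higher, while sugar transport and invertases as a list had 13 of 60 higher and 7 lower (median 0.19, percentile 37.9). In the abscisic acid list 6 of 52 were higher and 2 lower (median 0.15, percentile 45.8; 3 and 3 under TMM scaling), and the stress protein TAS14 (Unigene24327) was 25.4-fold higher. Redox enzymes had 13 of 64 higher and 2 lower (median 0.37, percentile 92.7, and 99.1 with 1 sequence per name), with cytosolic ascorbate peroxidase (Unigene3918) 4.19-fold higher. Cell cycle and DNA replication sequences had 41 of 204 higher and 4 lower (32 and 10 under TMM scaling). Their median was 0.31 at percentile 98.3, which was 42.5 with no level filter and 78.6 with 1 sequence per name. A sequence named licensing factor MCM3 (Unigene11968), whose Nr hit is instead mcm2-like, was 8.20-fold higher.

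In the phenolamide and polyamine list 8 of 43 were higher and 4 lower (6 and 6 under TMM scaling; median -0.03, percentile 2.11, and 7.09 with 1 sequence per name), with agmatine coumaroyltransferase-2 (Unigene16195) at 2 and 464 fragments, a ratio of 190 with an interval from 65.3 to 1965. Nicotine biosynthesis had 2 of 5 higher and none lower, 1 higher under TMM scaling (median 0.92, interval -0.76 to 1.85, percentile 98.1). Ornithine decarboxylase (Unigene24007), its most abundant member, had a log2 ratio of -0.76. It held 1538 of the list's 1541 CPM in mock and 911 of 919 in infected. The other members lay near the level filter, and the median of 0.92 rests on them. With a mean of at least 5 CPM the median, at percentile 10.2, was the ratio of ornithine decarboxylase itself. Among transcription factors, 3 of 65 bHLH sequences were higher and 13 lower (1 and 15 under TMM scaling; median -0.24, percentile 0), 6 of 55 NAC higher and 4 lower (median 0.28, percentile 86.5), and 8 of 60 MYB higher and 5 lower (median 0.03, percentile 6.17, and 1.46 with no level filter; 7 and 9 under TMM scaling). MYB21 (Unigene11902), whose Nr hit is instead a TT2-like factor, was 15.7-fold higher. The auxin list had 26 of 173 higher and 30 lower (median 0.03, percentile 0.205, and 10.5 with a mean of at least 5 CPM); 7 of its members are also glutathione S-transferases. Gibberellin, cytokinin and brassinosteroid sequences had 16 of 54 higher and 1 lower (13 and 4 under TMM scaling; median 0.21, percentile 47.3, and 0.51 at 99.2 with 1 sequence per name), with a gibberellin 2-beta-dioxygenase (Unigene23451), which inactivates gibberellins, 8.45-fold higher.

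Resistance proteins had 9 of 141 higher and 5 lower (6 and 8 under TMM scaling; median -0.08, percentile 0.01, and 3.47 with a mean of at least 5 CPM), calcium and MAP kinase signalling 10 of 162 and 4 (8 and 7 under TMM scaling; median 0.19, percentile 33.1), cell wall growth 35 of 269 and 18 (29 and 29 under TMM scaling; median 0.15, percentile 6.79), starch metabolism 3 of 50 and 4 (3 and 6 under TMM scaling; median 0.02, percentile 6.61), senescence and autophagy 3 of 46 and 0 (3 and 2 under TMM scaling; median 0.11, percentile 21.2), and U-box and RING ligases 55 of 428 and 16 (median 0.21, percentile 52.9, but 99.8 with no level filter and 1.78 with a mean of at least 5 CPM). The trichome list, in which 30 of 32 members are lipid-transfer proteins and so mark more than trichomes, had 11 higher and none lower (10 and 1 under TMM scaling; median 0.70, percentile 99.97, and 96.5 with 1 sequence per name). The organelle list had 6 of 163 higher and 15 lower (4 and 30 under TMM scaling; median -0.30, percentile 0), and 64 of its members are also light-reaction sequences, many of them nuclear genes. Virus and transposon names had 9 of 124 higher and 14 lower (median -0.15, percentile 0, and 30.2 with 1 sequence per name). The list of fungal names, matched on Nr and Swiss-Prot names only, held 0 sequences. This reflects the annotation, since the Nr hits name no fungus, and not the sample.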
